A study of Drosophila melanogaster with 3 samples.

How the data were processed

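Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map ORC2 in asynchronously growing ML-DmBG3-c2 (BG3) cells, a Drosophila melanogaster line derived from the larval central nervous system. ORC2 is a subunit of the origin recognition complex, the protein complex that binds chromatin at replication origins and there loads the MCM helicase. Per the labels, the antibody was a crude rabbit polyclonal serum against the whole purified ORC2 protein. The labels name 2 ChIP libraries and 1 input DNA library. The ChIP libraries carry different extraction numbers, but nothing in the labels says that they came from separate cultures, so differences between them may be technical.

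Peaks were called with PeakSeq, per the source field of each file, on FlyBase release 5 of the genome, per the file headers. PeakSeq looks for intervals with more ChIP reads than a control. The aligner, the read depth, the thresholds and the use made of the input library are not given in the sources used here. The deposited files hold 1 peak list for each ChIP library and 1 list for the series. Each peak has a start, an end and a score. The score is the authors' own value per peak, and the deposited files do not name the quantity or say what it is relative to; all scores exceed 1. It was used only to rank, filter or compare peaks. No read count stands behind any value, so depth is unknown and no interval for a peak's score can be given. Intervals on shares of peaks are exact Clopper-Pearson 95% intervals, cover counting error only, and treat peaks as independent. A peak list of the input library was not used here, so ChIP and input were not compared.

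The series list was tested against the replicate lists. Its 4477 intervals all ran from the outer start to the outer end of overlapping peaks of both replicates, and no overlapping pair was missing from it. In 4475 of them the score was a mean of the overlapping replicate scores within 0.0001. The series list is therefore the set of peaks called in both replicates, widened to their joint extent, and it carries no SD or n of its own. The smallest gap between neighbouring peaks was 200 bp in each replicate list, so signals closer than that stand as 1 peak.

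The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. A peak of 1 replicate was called shared when it overlapped a peak of the other by at least 1 bp. Chance overlap came from 1000 rotations of 1 list within each chromosome arm or scaffold, a permutation that keeps the spacing of peaks. Scores of shared peaks were compared by Spearman's rho with 100000 permutations. Density per Mb was computed over the span from the first to the last peak of any list on an arm, since arm lengths were not given with the files. Arms were tested by 10000 rotations of the joined arms 2L, 2R, 3L, 3R, X and 4, two-sided, with Benjamini-Hochberg adjustment over the 6 arms. Distances to the nearest peak were set against 1000 uniform placements within arms, one-sided; where neighbouring peaks were merged, the random positions were kept at least the merging distance plus a mean peak width apart. The 2 Mb beside the centromere (the high coordinates of 2L, 3L and X, the low coordinates of 2R and 3R) were compared with the rest of the arm by 10000 rotations within arms, two-sided. Rotation p-values describe the placement of peaks in these lists, not variation between samples. The smallest p these tests can give is 0.001 with 1000 rotations or placements, 0.0002 with 10000 two-sided rotations and 1e-05 with 100000 permutations.

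The code was tested on simulated lists as long as the real ones. For the replicate overlap, 2458 of 2500 planted shared peaks were recovered after chance was subtracted. With a planted X to autosome ratio of 0.7 in 20 lists, the mean recovered ratio was 0.701, but the rotation of joined arms called only 7 of the 20, and shuffling 1 Mb blocks between arms called 20 of 20; with no change planted, each called 0 of 20. With a planted ratio of 0.5 beside the centromere, 20 of 20 lists were called, against 1 of 20 with none planted. Both changes were planted in the same lists, and fewer rotations and shuffles were run than for the real lists. The simulated peaks were placed uniformly, whereas the real peaks are clustered. The rates of calls, true or false, may therefore differ in the real lists.

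The main tests, the peaks to be named and the alternatives were fixed before the data were examined, apart from additions identified as such. The rule names the 15 peaks of the series list with the highest score, its 5 widest peaks and its 3 densest 100 kb windows. Also outside that plan were the bins by width and score and the comparison of shared with unshared peaks. The same holds for the tests on the 50 highest-scoring peaks, the window counts in random placements and the share of neighbours within 1 kb. Alternatives were a reciprocal overlap of at least 50%, midpoints within 500 bp, peaks scoring above the median, equal list lengths, uniform placement, the large arms alone, each replicate list in place of the series list, merging of neighbours and other distances from the centromere. Planned comparisons with transcription starts, gene features and lists of genes (replication, cell cycle, ribosomal protein, histone, homeotic, neural, glial, blood, chorion, chemoreceptor, heat shock, dosage compensation and chromatin genes) were not run, because the gene table at hand is of genome release 6 and coordinates were not converted between releases. Peaks are therefore given by position, and whether each lies in a gene, exon, intron or UTR was not analysed here.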

Results

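ORC2 binding was mapped in BG3 cells by ChIP-seq in 2 libraries, with 1 input DNA library named beside them. The deposited peak lists held 8494 ORC2 peaks in replicate 1 and 5905 in replicate 2 (mean 7200 ± 1831, SD, n = 2), and 4477 peaks in the series list. Replicate 1 peaks covered 1.27 Mb of the genome, replicate 2 peaks 0.785 Mb and the series list 1.06 Mb. The called ORC2 intervals were short. The median width was 103 bp in replicate 1 (quartiles 56 and 195 bp) and 99 bp in replicate 2 (48 and 171 bp). In the series list it was 186 bp (124 and 302 bp). The thresholds of the calls are not given, so these widths cannot be read as the extent of ORC2 binding. Peaks of 30 bp or less made up 14.7% of replicate 1 and 17.8% of replicate 2, but 0.313% of the series list. Series intervals span the overlapping peaks of both replicates, so their larger width and the rarity of short ones are partly built in. The median score was 2.92 in replicate 1, 3.04 in replicate 2 and 3.17 in the series list. The number of reads behind the lists is unknown, so the 1.44-fold difference in list length cannot be set against depth.

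The first comparison asked how far the 2 ChIP libraries placed ORC2 at the same sites. Of the replicate 2 peaks, 4583 of 5905 overlapped a replicate 1 peak, or 77.6% (95% exact interval 76.5 to 78.7). Of the replicate 1 peaks, 4494 of 8494 overlapped a replicate 2 peak, or 52.9% (51.8 to 54.0). Rotation of 1 list within each arm or scaffold gave mean overlaps of 1.91% and 1.33%, with highest values of 2.62% and 8.65% (one-sided rotation permutation, p = 0.001 for each, the smallest 1000 rotations can give). Peaks called in both libraries had larger median widths and scores than those called in 1 library. In replicate 1 the median width was 166 bp for 4494 shared peaks and 61 bp for 4000 unshared peaks, and the median score was 3.22 against 2.64. In replicate 2 the median width was 119 bp for shared peaks and 33 bp for the 1322 unshared peaks, and the median score was 3.08 against 2.84. With each list cut into 5 bins by width, the shared percentage of replicate 1 peaks rose from 9.89% (8.51 to 11.4) in the narrowest bin to 88.9% (87.3 to 90.3) in the widest, and that of replicate 2 peaks from 40.7% (37.9 to 43.6) to 98.1% (97.2 to 98.8). By score, the shared percentage of replicate 1 peaks rose through all 5 bins, from 33.7% to 68.3%, whereas that of replicate 2 peaks went from 68.3% in the lowest bin to 84.8% in the fourth and was 74.6% (72.0 to 77.1) in the highest. When overlap had to reach 50% of both peaks, 33.9% of replicate 1 and 48.8% of replicate 2 peaks were shared (p = 0.001 for each by the same permutation).

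**Figure D1:**
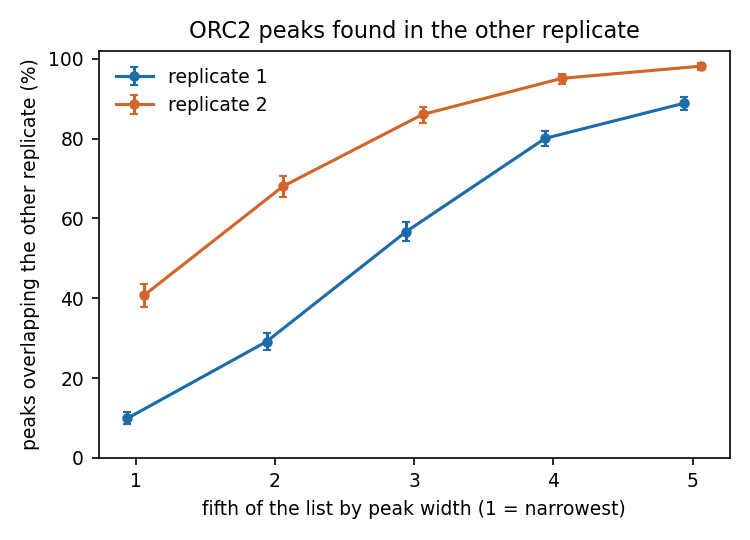
Percentage of ORC2 peaks that overlap a peak of the other replicate (y axis) in 5 equal bins of peak width (x axis, narrowest to widest), for replicate 1 and replicate 2; bars are 95% exact binomial intervals. Replicate 1 goes from 9.89% to 88.9% and replicate 2 from 40.7% to 98.1%.

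At the 4477 sites called in both libraries, the scores ranked alike. Across these peaks, which are not independent replicates, Spearman's rho between replicate 1 and replicate 2 was 0.758 (two-sided permutation, p = 1e-05, the smallest 100000 permutations can give), and Pearson's r of the log2 scores was 0.782. The widths of the same peaks correlated with a rho of 0.634. The median score at these sites was 3.22 in replicate 1 and 3.09 in replicate 2, and the replicate 2 score was the higher at 42.6% of them.

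**Figure D2:**
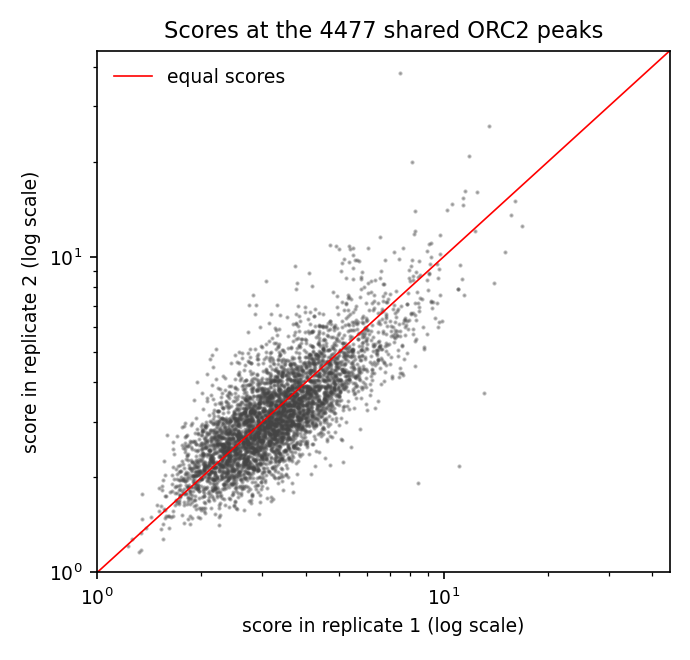
Score of each of the 4477 shared ORC2 peaks in replicate 1 (x axis, log scale) and replicate 2 (y axis, log scale), the authors' score without a stated unit; the line marks equal scores. Most points follow the line (rho 0.758), and the topmost point is the 13 bp peak on 2L at 7.48 in replicate 1 and 38.3 in replicate 2.

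The 15 highest-scoring peaks of the series list, with scores from 12.2 to 22.9, lay on 2L (4 peaks), 3L (4), 3R (3), X (2), 2R (1) and the heterochromatin scaffold 3RHet (1). All 15 were narrower than 200 bp, with a median width of 100 bp. The order is that of the authors' score and is not a ranking of binding strength. Very high scores did not mark repeatable calls in replicate 2, where 22.0% of the 50 highest-scoring peaks were shared, against 77.6% of the list. In replicate 1 the values were 42.0% and 52.9%. The first was a 13 bp interval on 2L at 22247855 to 22247867, where replicate 1 scored 7.48 and replicate 2 scored 38.3. The next was on 2R at 978022 to 978090, with 13.5 in replicate 1 and 26.1 in replicate 2. The peak on 3L at 5790517 to 5790583 scored 11.8 and 20.8. The replicates differed less on 3RHet at 1808469 to 1808591, with 16.04 and 15.05, and on 2L at 13642032 to 13642096, with 12.3 and 12.1. On the X the highest was 6004018 to 6004187, with 16.8 in replicate 1 and 12.5 in replicate 2, followed by 4593548 to 4593647 with 15.04 and 10.34. On 3R the highest were 26696355 to 26696463, with 12.5 and 16.1, and 18619788 to 18619973, with 8.12 and 19.97. The 15 included peaks close to the centromere side of the assembled arms, among them 24529162 to 24529277 on 3L, with 15.7 and 13.5, and 22961107 to 22961237 on 2L, with 10.3 and 14.0.

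The widest shared ORC2 peaks were not set apart by their scores. The 5 widest of the series list measured 1269 to 1841 bp and scored 2.33 to 4.07. These scores lay on both sides of the median of the series list, 3.17 (quartiles 2.58 and 3.96). The peaks named above were chosen for high scores, so their scores are no measure for wide peaks. The widest was on 2L at 12010830 to 12012670, built from 1 replicate 1 peak with a score of 3.13 and 2 replicate 2 peaks with a mean of 3.06. It was followed by X at 1508320 to 1509846 (1527 bp), 3L at 2823246 to 2824586 (1341 bp), 3R at 21867357 to 21868676 (1320 bp) and 2L at 2752215 to 2753483 (1269 bp). The X interval of 1527 bp joined 2 peaks of each replicate, and the 3R interval joined 1 replicate 1 peak and 3 replicate 2 peaks. The widest peak of replicate 1 (2539 bp) and that of replicate 2 (15002 bp) were wider than any series interval, so neither was shared.

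The next comparison was between chromosome arms. ORC2 peaks were found on all 6 assembled arms. In the series list the density ran from 33.0 peaks per Mb on chromosome 4 and 33.6 on 2L to 41.2 on 2R, with 34.3 on the X, 38.7 on 3L and 37.9 on 3R. In the replicate lists the mean density was 53.4 ± 12.5 peaks per Mb on 2L, 62.3 ± 14.9 on 2R, 61.0 ± 16.5 on 3L, 57.9 ± 14.8 on 3R, 59.8 ± 14.1 on the X and 59.8 ± 11.1 on chromosome 4 (SD, n = 2), a spread that reflects the lengths of the lists. No arm passed the test in the series list: adjusted p was 0.67 for 2L and 2R, 0.74 for 3L and X, and 0.76 for 3R and 4 (two-sided rotation permutation, Benjamini-Hochberg over 6 arms). The X to autosome density ratio was 0.907 in the series list, 1.01 in replicate 1 and 1.03 in replicate 2 (rotation permutation, p = 0.38, 0.65 and 0.56), and 95% of rotations of the series list lay between 0.824 and 1.27. In simulated lists of unclustered peaks this test called a ratio of 0.7 in only 7 of 20 lists, so it can miss a difference of that size. Its power for single arms was not checked. With 1 Mb blocks shuffled between arms, a test added after the data were seen, p for the series list was 0.18. X peaks were shared between replicates less often than peaks of the large autosomal arms, at 49.3% against 55.0% of replicate 1 peaks and 70.9% against 80.2% of replicate 2 peaks; on chromosome 4 the values were 48.8% (37.6 to 60.1) and 63.5% (50.4 to 75.3).

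**Figure D3:**
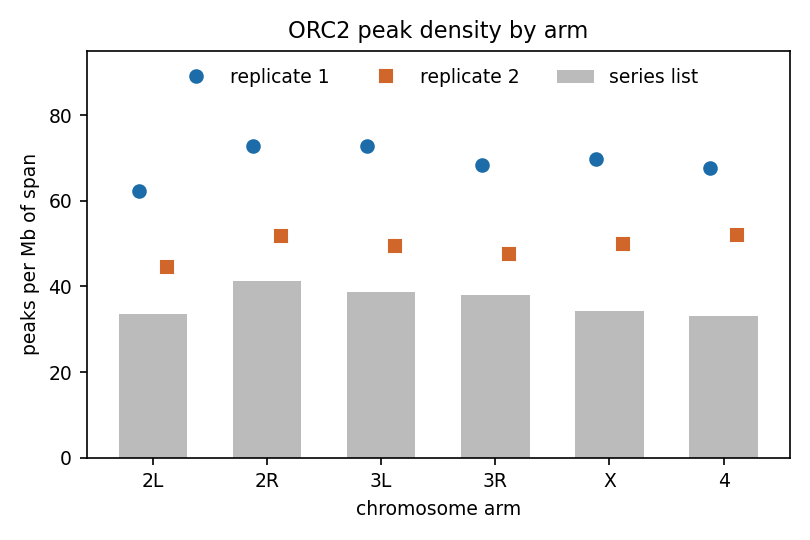
ORC2 peaks per Mb of span (y axis) on each chromosome arm (x axis); bars show the series list, circles replicate 1 and squares replicate 2. The series list ranges from 33.0 on chromosome 4 to 41.2 on 2R, and replicate 1 lies above replicate 2 on every arm.

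Along the large arms, ORC2 peaks were sparse beside the centromere. In the series list, the 2 Mb at the centromere side of 2L, 2R, 3L, 3R and X together held 204 of 4409 peaks, a density of 20.4 per Mb and 0.527 times that of the rest of the arms (two-sided rotation permutation, p = 0.0002, the smallest 10000 rotations can give; 95% of rotations lay between 0.774 and 1.23). The ratio was 0.608 in replicate 1 and 0.608 in replicate 2, with the same p. It was 0.410 for the first 1 Mb and 0.764 for 4 Mb. The arms were not alike. In the series list the density beside the centromere was 13 per Mb against 44.1 in the rest of 2R, 13.5 against 41.0 on 3L, 17.5 against 35.9 on the X and 19 against 35.02 on 2L. On 3R it was 39 against 37.8, a ratio of 1.03, and the 3R ratios in replicate 1 and replicate 2 were 1.05 and 0.988. The test was made over the 5 arms together and not for each arm, and how much of this sequence reads can be assigned to was not analysed here.

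ORC2 peaks lay closer together than positions placed uniformly along the arms. The placements drew on the whole span of each arm, including the sequence beside the centromere. How much of that span reads can be assigned to was not analysed here, so its part in the spacing stays open. The median distance from a peak of the series list to its nearest neighbour was 3567 bp, against 9311 bp in random placements, a ratio of 0.383 (one-sided placement permutation, p = 0.001, the smallest 1000 placements can give). A neighbour lay within 1 kb for 26.0% of peaks, against a mean of 7.06% and at most 8.45% in 100 random placements. The ratio was 0.322 in replicate 1 and 0.322 in replicate 2. It stayed below 1 when peaks within 1 kb were merged (0.583), when peaks within 5 kb were merged (0.787, an alternative added after the data were seen) and when only peaks above the median score were kept (0.510), each with p = 0.001 by the same permutation.

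**Figure D4:**
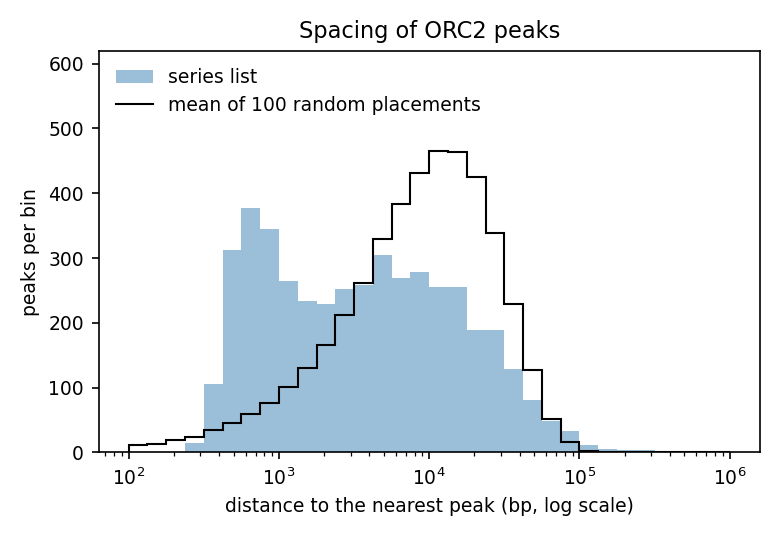
Distance from each ORC2 peak of the series list to its nearest neighbour (x axis, bp, log scale) and number of peaks per bin (y axis); the black line is the mean of 100 random placements. Within 1 kb lie 26.0% of peaks, against 7.06% at random. Below about 0.3 kb the list has fewer peaks than random, around 10 kb fewer again, and beyond 75 kb more.

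The densest 100 kb window of the series list was 12000001 to 12100000 on 3R, with 24 peaks (36 in replicate 1 and 26 in replicate 2). It was followed by 9800001 to 9900000 on 2R with 20 peaks (26 and 21) and 500001 to 600000 on 3L with 17 peaks (30 and 18). The mean over 1204 windows was 3.70 peaks, and the highest count in any window of 1000 random placements was 16, so that 3 windows exceeded it. At the other extreme, 201 windows (16.7%) held no peak of the series list, and the variance of the window counts was 2.85 times their mean.

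**Figure D5:**
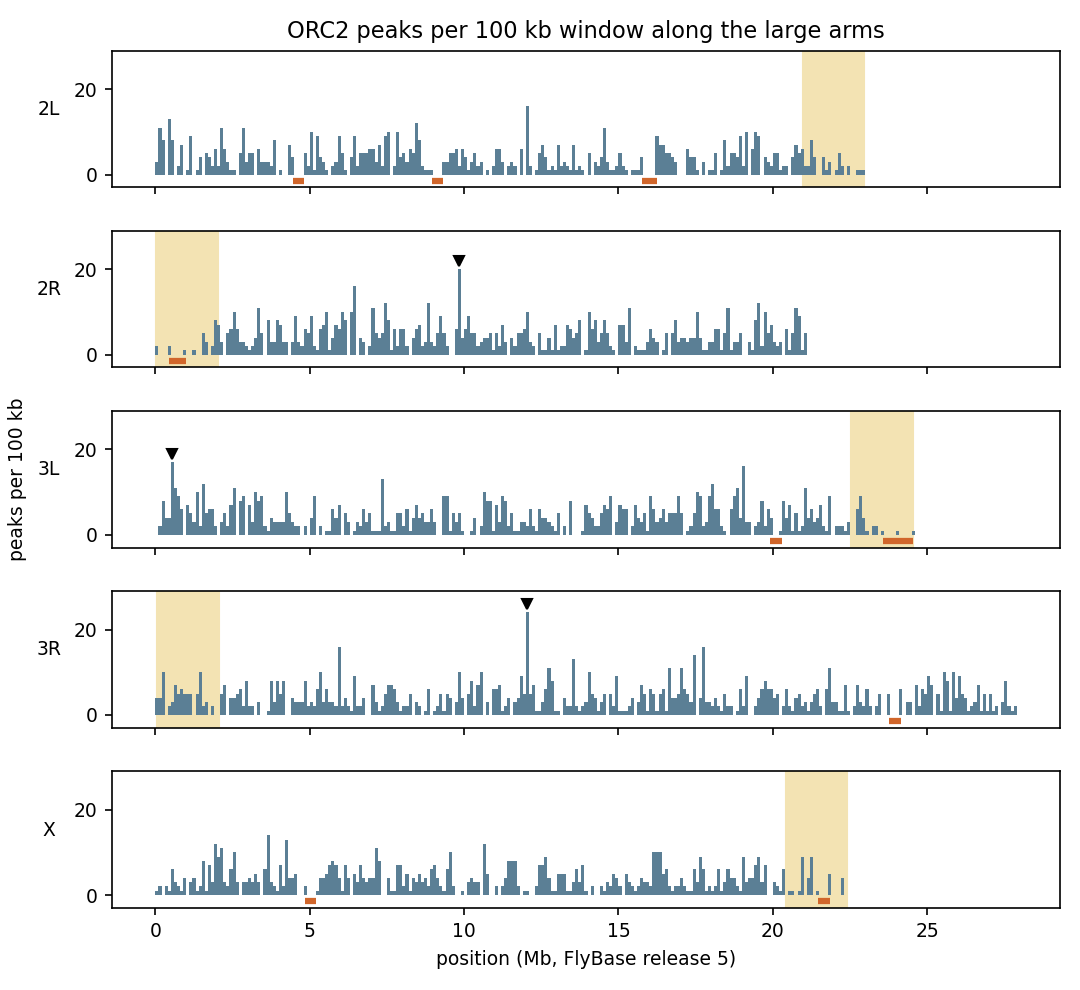
ORC2 peaks of the series list per 100 kb window (y axis) along 2L, 2R, 3L, 3R and X (x axis, Mb of FlyBase release 5). Triangles mark the 3 densest windows (24 on 3R, 20 on 2R, 17 on 3L), orange lines the 10 longest stretches without a peak, and shading the 2 Mb at the centromere side.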

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

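Peaks outside the 6 assembled arms entered the test of replicate overlap, but not those of density, clustering or the centromere side. Such peaks were present in every list: 206 peaks in replicate 1 (2.43% of the list, 95% exact interval 2.11 to 2.78), 85 in replicate 2 (1.44%, 1.15 to 1.78) and 28 in the series list (0.625%, 0.416 to 0.903). Across the lists they lay on the heterochromatin scaffolds 2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet and on unplaced sequence (U). Replicate 1 had 94 peaks on U and replicate 2 had 15, against 2 in the series list. Only 14.1% (9.64 to 19.6) of the replicate 1 peaks and 32.9% (23.1 to 44.0) of the replicate 2 peaks on these scaffolds were shared, against 52.9% and 77.6% of the full lists. YHet had 1 replicate 1 peak and none in the other lists. Density in the series list was 12.7 peaks per Mb of span on XHet (1 peak), 9.19 on 2LHet (2 peaks), 5.14 on 3LHet, 2.39 on 3RHet, 1.55 on 2RHet and 0.201 on U, where the assembled arms had 33.0 to 41.2. The span runs between the outermost peaks, and was only 0.0785 Mb on XHet and 0.218 Mb on 2LHet. Few peaks can thus give a short span and a raised density, so the scaffolds cannot be ranked by these values. No input values were used here, so no control level stands beside these counts.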

How the results depend on the processing

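The replicate overlap, the score correlation, the clustering and the low density beside the centromere kept their direction and stayed past the threshold under every alternative run for them, including each replicate list in place of the series list. The overlap ranged from 33.9% (reciprocal overlap) to 60.3% (midpoints within 500 bp) of replicate 1 peaks and from 48.8% (reciprocal overlap) to 85.9% (peaks of at least 50 bp, added after seeing the data) of replicate 2 peaks. With a reciprocal overlap of 50%, 67.3% of the series list was found in both replicates, not 100%, by the construction of its widened intervals. Merging peaks within 5 kb, also added later, left the clustering ratio at 0.787 against random lists kept as far apart. The X to autosome ratio, not past the threshold in any setting, crossed 1 when the list of replicate 1 (1.01) or replicate 2 (1.03) was used and among peaks above the median score (1.18). Single arms, none past the threshold in any setting, crossed the mean of the rotations too. With replicate 1 alone, 3R stood at 0.989 and X at 1.01, with chromosome 4 still below the mean at 0.976; with replicate 2 alone, 3R at 0.978, X at 1.03 and chromosome 4 at 1.07; among peaks above the median score, 3L at 0.954, 3R at 0.996, X at 1.13 and chromosome 4 at 1.25; by bases covered, chromosome 4 at 1.004; and with neighbours within 5 kb merged, chromosome 4 at 1.02. For the X, the series list stands below the replicate lists because it holds only shared peaks, and X peaks were shared less often. The shares were 49.3% against 55.0% on the large autosomal arms in replicate 1, and 70.9% against 80.2% in replicate 2. The cause of the other crossings was not tested. Restricting the series list to peaks of both replicates removes nothing and is no test. The alternatives on transcription starts, gene features and gene lists were not run. Leaving out a replicate gives no value for the comparison of the replicates. No paired analysis was possible because the only other group is a single input library. Unknown read depth limits what the shorter list of replicate 2 can show.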

Other observations

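The tests on single-replicate peaks and on long gaps, and the block shuffles, were chosen after results were seen; those on X peaks by width and score were written down before their results. An earlier form of the gap test, which rotated shared peaks too, was biased towards a low value and was dropped.

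The longest stretches without a peak of the series list were on 2R at 432444 to 978021 (546 kb), 3L at 24021657 to 24529161 (508 kb) and 2L at 15762812 to 16257153 (494 kb). They were chosen for lacking shared peaks, so shared peaks are absent from them by choice. Unshared peaks lay nearer to peaks of the series list than rotations placed them, as given below. Stretches without series peaks therefore tend to hold fewer unshared peaks than the mean density gives, and the counts that follow are no separate test. The 10 longest held 72 replicate 1 peaks, where the arms' mean density of unshared peaks gives 136, and 25 replicate 2 peaks against 45.2. In each replicate 9 of the 10 were below their expected number. The exceptions were 2L at 8950163 to 9330628, with 14 replicate 1 peaks against 10.8, and the 2R stretch, with 6 replicate 2 peaks against 5.34 but 9 replicate 1 peaks against 17.2. The 3L stretch at 19922408 to 20295452, with 12 replicate 1 peaks against 12.7, was barely below. So was the 3L stretch at 24021657 to 24529161 in replicate 2, with 5 peaks against 5.08. On 3R, 23774583 to 24151993 held 1 replicate 1 peak against 11.4 and no replicate 2 peak against 3.21.

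Gaps in replicate 2 could be sites missed in that library alone. The 20 longest on the large arms (249 to 495 kb, 6.11 Mb in all) held 62 unshared replicate 1 peaks, where rotations of the unshared peaks within arms gave a mean of 193 and a lowest value of 116 (one-sided rotation permutation, p = 0.001), which argues against it. Chance spacing of clusters is not excluded. With unmerged peaks, 1000 random placements reached at most 1 gap as long. With peaks merged within 1 kb they reached 5, and within 5 kb 10. With 10 kb they reached 28, with a mean of 14.6, and a share of 0.087 of placements had as many as 20. With 20 kb they reached 76, with a mean of 57.0. Sequence beside the centromere is excluded for most gaps, since 13 of the 20 lay over 4 Mb from the centromere side. It stays open for the 7 gaps nearer to it, a share of 35% (15.4 to 59.2) where 16.8% of the arms lies within 4 Mb. Repeats to which reads cannot be assigned and a lower occupancy of ORC2 were not tested.

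Peaks called in 1 replicate only might all be calls placed at random. Against this, on the 5 large arms, 3781 replicate 1 peaks without a partner lay a median of 4811 bp from the nearest peak of the series list, below the lowest of 1000 rotations (11267 bp), and 1242 of replicate 2 lay at 4370 bp (lowest 10464 bp). A median cannot tell whether a part of these peaks was placed at random, so that stays open on the large arms. The test left out chromosome 4 and all sequence outside the arms, where random calls stay open as well. Short enrichments near the detection limit remain a candidate explanation: the widest of 5 bins was shared more often than the narrowest by 79.0 percentage points in replicate 1 and 57.4 in replicate 2, and a narrow interval also has less room to overlap. With midpoints within 500 bp counted instead, the share still went from 23.7% to 89.9% in replicate 1 and from 61.4% to 98.3% in replicate 2. Across 1191 windows of 100 kb, counts of peaks found only in replicate 1 and of those found only in replicate 2 correlated with a rho of 0.414, a value across windows without a test. No biological explanation was tested, since both libraries belong to 1 group.

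Peaks on the X scored higher than those on the large autosomal arms, yet fewer were shared. The median score was 3.33 on the X and 2.83 on the autosomal arms in replicate 1, and 3.21 and 3.001 in replicate 2 (1 Mb blocks shuffled between arms, two-sided permutation, p = 0.0002 and 0.0028). The shared percentage of the X minus that of the autosomal arms was -5.68 points in replicate 1 and -9.31 points in replicate 2 (same permutation, p = 0.0006 and 0.0002), and the autosomal arms ranged from 53.3% to 56.8% and from 77.5% to 82.1%. Narrower peaks on the X (median 100 against 106 bp, and 93 against 100 bp) do not account for it: within 10 bins of width the Mantel-Haenszel odds ratio of being shared was 0.814 (95% interval 0.708 to 0.935) and 0.563 (0.472 to 0.673). The X did not hold more low-scoring calls. Its density ratio to the autosomes was 1.39 and 1.18 among peaks above the median score, and 0.682 and 0.899 below it. This split largely restates the higher median score on the X, and what the score measures is not stated. It therefore cannot exclude more weakly supported calls on the X. On chromosome 4, which was not tested against the other arms, 48.8% of 82 replicate 1 peaks (37.6 to 60.1, an interval that includes the autosomal 55.0%) and 63.5% of 63 replicate 2 peaks (50.4 to 75.3, wholly below the autosomal 80.2%) were shared. Fewer reads on the X, from a lower copy number or from library preparation, may raise a ratio-like score and make calls less repeatable; this was not tested, since no read or input counts were used and the labels leave the sex of the line open.

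The highest score of each replicate belonged to a peak absent from the other: 224.6 on U in replicate 1 and 643.7 in a 3 bp interval on the X in replicate 2. Of the 50 highest-scoring peaks, 22.0% were shared in replicate 2 (11.5 to 36.0; Fisher's exact test against the rest of the list, two-sided, p = 7.7e-17) and 42.0% in replicate 1 (28.2 to 56.8; p = 0.15). Of the unshared ones among them, 13 of 29 in replicate 1 (44.8%) and 7 of 39 in replicate 2 (17.9%) lay outside the assembled arms, against 2.43% and 1.44% of the lists. The unshared ones had median widths of 52 and 56 bp, against 106 and 67 bp for the shared ones among the 50 (two-sided permutation, p = 0.00066 and 0.76) and 103 and 99 bp in the lists.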
